A study of Mus musculus with 12 samples.

How the data were processed

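Testes of mouse embryos at embryonic day 15.5 were profiled on 12 Affymetrix arrays of 45101 probe sets, 3 for each of wild type and Dmrt1 knockout in 129Sv and in B6, and total RNA was labelled with biotin, per the labels, although the growth protocol names P28 for the embryos. The deposited values are intensities that the authors summarised per probe set with GCRMA, a model that corrects background by probe sequence, normalises quantiles and summarises probes, per the submitters' processing notes; its version and settings are not given in the sources used here. The deposited values had no entry below 1 and medians near 18 on every array, so they were read as linear intensities and log2 was taken here. The design written before the values were seen had assumed log2 values, and the test itself stayed the same. No other columns of sample values were in the table. Groups and replicate numbers were taken from the description of each sample. Depth in the sense of counts does not exist for arrays, and their number, 3 per group, limits the precision.

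Probe sets were named through the platform annotation supplied with the table, with symbols updated by Entrez identifier through RefSeq genes of GRCm38.p6. Of the probe sets, 34958 had 1 gene, 932 had several and 9211 had none, and only those with 1 gene were named. Control probe sets, 13 with a gene name among them, stayed out of the tests. The 34958 probe sets covered 18193 genes, and a gene was represented by the probe set with the highest mean over the 12 arrays. Genes with a log2 value of at least 4 (an intensity of 16) in at least 3 arrays were tested, 12726 in all, of which 7712 had several probe sets. Below a log2 value of 4 the intensities carry little signal, so a fold change between a group mean above 4 and one below it was computed against 4 and is given as "at least". Where both group means lay below 4, the fitted fold is given. Log2 differences beside folds given as "at least" are the fitted ones and include values below 4.

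A linear model of the 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, 8 residual degrees of freedom and 6.71 prior ones), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with 0.05 as the threshold. The contrasts were knockout minus wild type within 129Sv and within B6, the difference of these effects (129Sv minus B6), their average, and 129Sv minus B6 within wild type and within knockout. Errors of log2 differences are standard errors from this fit. Dmrt1 was also compared by a two-sided exact permutation test. Gene lists, 25 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. With an estimated correlation no list in any contrast passed. Dnmt3b is in no list and was named outside the rule below. Besides it, Dmrt1 and members of those lists, genes were named by a rule also fixed before the data were examined. It takes up to 10 genes in each direction with the largest log2 difference for the 3 main comparisons (knockout in 129Sv, knockout in B6 and strain in wild type), and up to 6 for the others, among those past the threshold with a mean log2 value of at least 5 in the higher group and, except for the difference of effects, no overlap between the arrays of the groups. Chromosomal order of genes was taken from the RefSeq table only for which genes neighbour each other.

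The fit and the list test were run on simulated data drawn independently between genes with the real genes' means and spreads, with 200 of the 12726 genes changed; the other scripts were not tested in this way. In the 129Sv knockout contrast the fit found 26% of genes changed by 0.5 on the log2 scale, 86% of those changed by 1 and all changed by 2 or 4, with 7.7% false calls. In the B6 knockout contrast the shares were 22%, 80% and 100%, with 5% false calls. In the contrast of the knockout effects the shares were 16%, 58%, 98% and 100%, with 6.2% false calls. In a simulated set of lists, 1 list of 16 genes shifted by 0.7 was found by camera (adjusted p = 1.76e-32) and by camera with an estimated correlation (2.82e-05). None of 24 unshifted lists was called by camera at the preset correlation. In the real data the estimated correlation was 0.445 in the pluripotency list and 0.428 in the male germ cell list, which these independent draws do not test.

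Alternatives, recomputed for the results they apply to, were other filters, other rules for probe sets, quantile normalisation and median centring of the deposited values, a floor at 4, no variance trend, array weights, a fit of only the groups compared, a 2-fold threshold, replicate number as a block, a number shared between titles as a random block, the title number before the strain as a covariate, and each array left out. The ratio of the 3′ to the 5′ Actb probe set as a covariate, and leaving out the 2 arrays where it was highest, were added after the data were examined.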

Results

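Gene expression was measured in mouse testes at stage E15.5 on 12 Affymetrix arrays, each hybridised with biotin-labelled total RNA. The sample labels give this stage, whereas their growth protocol names P28 for the embryos, and the labels were followed. The arrays fell into 4 groups of 3, wild type and Dmrt1 knockout in the 129Sv strain and wild type and Dmrt1 knockout in the B6 strain. Dmrt1 encodes a DM domain transcription factor that is present in germ cells and Sertoli cells of the fetal testis, and 129 strains are known for testicular teratomas, tumours that arise from fetal germ cells. Each array reported 45101 probe sets, and its median intensity lay between 17.3 and 19. Between 51.0% and 52.2% of the probe sets of an array exceeded an intensity of 16. Arrays of the same group correlated across probe sets with r between 0.983 and 0.998, and no array was a copy of another. The ratio of the 3′ to the 5′ probe set of Actb, which rises when RNA is degraded, was 6.30 in B6 knockout replicate 3, 5.24 in 129Sv knockout replicate 1 and 3.91 in 129Sv wild-type replicate 2, and between 1.99 and 2.79 on the other 9 arrays. In B6 the titles of wild-type and knockout replicate 1 share a number, as do those of replicate 2. The title of B6 wild-type replicate 3 has no such number and none before the strain code, unlike the other B6 titles. The last number of the titles runs from 1 to 3 in B6 knockouts, from 4 to 6 in B6 wild types and from 7 to 12 in 129Sv. Its meaning is not given in the sources used here. If it is an order of processing, strain and, within B6, genotype cannot be told apart from it. The titles differ between arrays of a group, but the labels do not state whether each array stands for a separate animal, so the p-values measure the spread between these samples. After probe sets were reduced to 1 per gene, 12726 genes were tested.

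Dmrt1 itself was lower in the knockout groups of both strains. In 129Sv its intensity was 166.6 ± 18.9 (SD, n = 3) in knockout testes and 1040 ± 132 (SD, n = 3) in wild-type testes, a geometric mean ratio of 16%. In B6 it was 74.4 ± 11.3 (SD, n = 3) in knockout and 985 ± 165 (SD, n = 3) in wild type, a ratio of 7.60%. The log2 differences were -2.64 ± 0.17 (SE, limma adjusted p = 4.72e-07) in 129Sv and -3.72 ± 0.17 (SE, limma adjusted p = 1.97e-08) in B6. In each strain all 3 knockout arrays lay below all 3 wild-type arrays, with a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. The knockout effect was larger in B6, and the difference of 1.08 ± 0.24 on the log2 scale passed the test (adjusted p = 0.045). Only 1 probe set of the array names Dmrt1, and the labels do not say which part of the gene was removed, and the series text speaks of a conditional removal while the samples are labelled knockout. The remaining signal, 64.0 to 181 on the knockout arrays, lay above the filter intensity of 16, which argues against background at that level. It cannot be assigned to cells that kept the gene, to deleted transcripts or to a higher background of this probe set. Whether the removal was complete is not given in the sources used here.

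**Figure D1:**
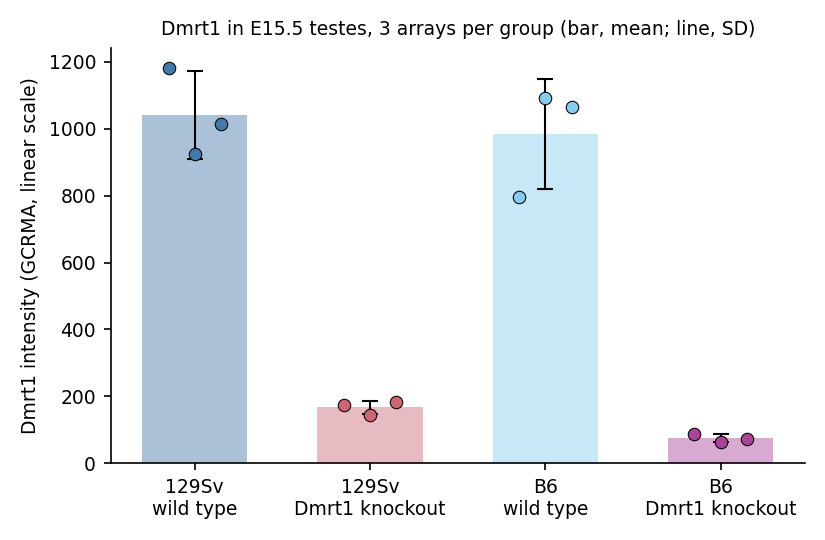
Dmrt1 intensity on a linear scale for each of the 12 arrays, with 3 points per group, bars for group means and lines for the SD. The knockout arrays lie between 64.0 and 181, and the wild-type arrays between 795 and 1183.

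The comparison of knockout with wild-type testes in 129Sv asked which genes depend on Dmrt1 in that strain, and many pluripotency genes rose. L1td1, an RNA-binding protein gene active in pluripotent cells, was 45.7-fold higher in the knockout (log2 difference 5.52 ± 0.43, SE, n = 3 per group, adjusted p = 1.37e-06). Otx2, a homeobox gene of the early epiblast and brain, was at least 26.2-fold higher (5.38 ± 0.37, adjusted p = 5.35e-07). Nanog, a core transcription factor of pluripotent cells, was 10.3-fold higher (3.37 ± 0.22, adjusted p = 4.72e-07), and Sox2, its partner in that network, was 7.17-fold higher (2.84 ± 0.25, adjusted p = 4.67e-06). Of the 24 tested genes in the pluripotency and early germline list, 16 rose, 1 fell and 7 did not pass. Adjusted over the list alone, 19 rose and 1 fell. The list was shifted upward against all other genes (camera adjusted p = 1.25e-15 with a preset correlation of 0.01, adjusted p = 0.477 with an estimated correlation). Gdf3 rose 12.9-fold, Esrrb 7.30-fold, Fbxo15 4.94-fold, Zfp42 3.82-fold and Tcl1 3.58-fold, while Klf4 fell 2.43-fold. Pou5f1, which encodes the pluripotency factor OCT4, differed by 0.57 ± 0.21 on the log2 scale and did not pass (adjusted p = 0.108).

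Signalling and lineage genes of the early embryo also changed in 129Sv. Among 17 genes of Nodal and activin signalling, 4 rose, namely Nodal (4.74-fold), Lefty1 (at least 2.87-fold), Tdgf1 (at least 5.44-fold) and Foxh1 (at least 1.97-fold), and Inhbb fell 1.34-fold. Among 7 genes of germ layer differentiation, Otx2 and Eomes (at least 4.80-fold) rose and Afp, the gene of alpha-fetoprotein, fell 3.10-fold. Neither list was shifted against all other genes (camera adjusted p = 0.159 and 0.416). Without a filter the germ layer list did pass (0.00981), and fry, which tests a list by itself, gave an adjusted p of 0.00342 and 0.00157. Among 15 genes of retinoic acid signalling, Crabp2, which encodes a retinoic acid binding protein, rose 7.53-fold and Rarg 1.77-fold, while Rxra fell 1.47-fold. The remaining genes with the largest rises in 129Sv were Svopl (at least 23.1-fold), Cdhr1 (at least 16-fold), Eras (13.7-fold), Trh (at least 11.1-fold), Apela (at least 10.3-fold), Prap1 (at least 6.60-fold) and Mep1b (at least 5.79-fold).

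Some genes of the male germ cell program fell in 129Sv. Of 16 tested genes in the list of male germ cell and piRNA pathway genes, which act in the silencing of transposons and in prospermatogonia, 4 fell and 12 did not pass, and 9 fell when adjusted over the list alone. The 4 depended on single arrays, with 1 falling without 129Sv knockout replicate 1 or 2, 9 without 129Sv knockout replicate 3, and 1 with the title number as a covariate. Tdrd9, an RNA helicase of the piRNA pathway, fell 4.38-fold (log2 difference -2.13 ± 0.48, adjusted p = 0.0118), Zbtb16, which encodes the stem cell factor PLZF, 3.69-fold, Piwil1 3.05-fold and Morc1 1.64-fold. The list was shifted downward (camera adjusted p = 0.000837, adjusted p = 0.477 with an estimated correlation). Of 13 general germ cell genes, Sohlh2 (7.49-fold) and Rnf17 (1.98-fold) rose, Brdt fell 3.47-fold, and 10 did not pass, among them Ddx4 at 0.02 ± 0.16 and Dazl at 0.41 ± 0.21 on the log2 scale. Of 20 meiosis genes, Hormad2 (2.36-fold), Smc1b (2.13-fold), Sycp1 (2.12-fold) and Rec8 (1.88-fold) rose and Tex15 fell 1.79-fold. Of 12 genes of GDNF signalling, Lhx1 (10.5-fold) and Etv5 (2.29-fold) rose, and the receptor gene Ret (at least 2.81-fold), Gdnf (2.40-fold) and Bcl6b (2.24-fold) fell. The genes with the largest falls were Dntt (at least 10.3-fold), Pcp4 (9.96-fold), Svs4 (at least 9.83-fold), Gzma (9.77-fold), Drc1 (9.35-fold), 4933402E13Rik (at least 9.06-fold), Dscaml1 (at least 8.75-fold), Adtrp (at least 7.21-fold), Rph3a (at least 6.54-fold) and Asb17 (at least 5.32-fold).

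Some somatic cell markers changed in 129Sv. Of 19 Sertoli cell genes, Cst9 (2.30-fold), Hsd17b3 (2.28-fold), Hsd17b1 (2.01-fold) and Inhbb (1.34-fold) fell and none rose, and the list was shifted downward (camera adjusted p = 0.0174, adjusted p = 0.477 with an estimated correlation). No endothelial gene of 11 passed on its own, while that list was shifted downward (camera adjusted p = 0.0116, adjusted p = 0.477 with an estimated correlation). Of 9 ovarian somatic cell genes, Rspo1 (3.02-fold), Lef1 (1.75-fold) and Sp5 (at least 1.57-fold) rose. Of 7 neuron and skeletal muscle genes, Tnni1 (2.29-fold) and Th (at least 2.08-fold) rose, with an upward shift of the list (camera adjusted p = 0.00851, adjusted p = 0.477 with an estimated correlation) that did not pass without 129Sv knockout replicate 1, 2 or 3 (0.0957, 0.0867 and 0.363). The count of 4 Sertoli cell genes that fell became 2 without 129Sv wild-type replicate 1 or 2 or knockout replicate 1 or 2. The Sertoli cell shift did not pass without 129Sv wild-type replicate 1 or knockout replicate 2 (0.0739 and 0.0867) or with the title number as a covariate (0.0656). Nor did the endothelial shift without 129Sv knockout replicate 2 (0.0603). No gene passed among 16 of macrophages and leukocytes, 10 of interstitial and peritubular cells, 8 of fetal Leydig cells, 8 of red blood cells, 4 of adrenal cortex and 30 of cell division. In all, limma called 1058 of the 12726 genes at an adjusted p under 0.05, 518 higher and 540 lower in the knockout. All 129Sv knockout titles carry the number 7 before the strain code, as does wild-type replicate 2, whereas the other 129Sv wild types carry 11; with that number as a covariate, which leaves 1 wild-type array of the knockouts' number, 347 genes passed. Leaving out a single array gave 607 genes without 129Sv wild-type replicate 1, 623 without 129Sv wild-type replicate 3, 652 without 129Sv knockout replicate 1, 596 without 129Sv knockout replicate 2 and up to 1561 without B6 knockout replicate 3.

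In B6 testes the knockout lowered genes of the male germ cell program. Dnmt3l, the cofactor of de novo DNA methylation in male germ cells, was 23.5-fold lower in the knockout (log2 difference -4.55 ± 0.52, SE, n = 3 per group, adjusted p = 0.000107). Tdrd9 was 11.8-fold lower (-3.56 ± 0.48, adjusted p = 0.000363), Piwil1, a PIWI protein gene, at least 7.10-fold lower (-3.20 ± 0.38, adjusted p = 0.000144), Morc1 5.46-fold lower (-2.45 ± 0.19, adjusted p = 4.07e-06) and Piwil4 5.37-fold lower (-2.43 ± 0.28, adjusted p = 0.000113). Of the 16 male germ cell and piRNA pathway genes, 13 fell, none rose and 3 did not pass, and 14 fell when adjusted over the list alone. The list was shifted downward with a median of -1.44 on the log2 scale (camera adjusted p = 5.45e-16, adjusted p = 0.254 with an estimated correlation). Of 13 general germ cell genes, 5 fell, namely Brdt (6.75-fold), Gtsf1 (6.17-fold), Dnd1 (2.69-fold), Taf7l (2.48-fold) and Mael (1.94-fold), and Sohlh2 (2.60-fold) and Rnf17 (1.41-fold) rose (camera adjusted p = 0.00202, adjusted p = 0.479 with an estimated correlation). That shift did not pass without B6 knockout replicate 3 (0.0952). The change of Rnf17 depended on its probe set, because the mean of its probe sets differed by -0.55 on the log2 scale. Ddx4 and Dazl, which mark germ cells in general, differed by -0.46 ± 0.16 and -0.13 ± 0.21 and did not pass (adjusted p = 0.0855 and 0.71).

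Meiosis genes fell more often than they rose in B6, as did the called genes as a whole, of which 31% were higher. Of 20, 7 fell, among them Tex12 (3.26-fold), Tex15 (3.17-fold), Sycp3 (2.39-fold) and Stra8 (2.37-fold), and Sycp1, Rec8 and Syce2 rose between 1.43-fold and 1.70-fold. The list was shifted downward (camera adjusted p = 0.0364, adjusted p = 0.481 with an estimated correlation), and this shift did not pass when any of 5 single arrays was left out (adjusted p up to 0.125). The pluripotency and early germline list was shifted upward in B6 as well, but 1 of the 3 knockout arrays lay at the wild-type level. Of its 24 genes, 11 rose, 3 fell and 10 did not pass, and 12 rose and 5 fell when adjusted over the list alone. L1td1 rose 7.78-fold (log2 difference 2.96 ± 0.43, adjusted p = 0.000573), Esrrb 3.39-fold, Tcl1 3.35-fold, Nanog 3.24-fold (1.70 ± 0.22, adjusted p = 0.000248) and Sox2 2.07-fold, and Tfcp2l1, Dppa4 and Klf4 fell between 1.84-fold and 2.72-fold. The upward shift of the list was near the threshold (camera adjusted p = 0.0364, adjusted p = 0.643 with an estimated correlation), and its call ended when the filter was raised to a log2 value of 6 (adjusted p = 0.11) or when any of 5 single arrays was left out (adjusted p up to 0.284). The mean log2 level of the list was 8.674 and 8.575 in B6 knockout replicates 1 and 2 and 7.65 to 8.101 in B6 wild types. It was 7.703 in B6 knockout replicate 3, the array with the highest Actb ratio. Of all 12 arrays it also had the lowest mean of the general germ cell list (7.767) and the highest of the endothelial (7.923), macrophage and leukocyte (7.58) and fetal Leydig cell (11.829) lists. Without that array the camera adjusted p was 1.51e-06. Nodal (2.86-fold), Lefty1 (at least 3.04-fold) and Lefty2 (1.49-fold) rose among the 17 Nodal and activin genes, and Lhx1 (5.33-fold) and Etv4 (at least 1.09-fold) rose while Ret (3.03-fold) and Gdnf (1.87-fold) fell among the 12 GDNF genes.

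The genes with the largest rises in B6 were Otx2 (at least 5.76-fold), L1td1, Svopl (7.06-fold), Lhx1, Dnaic1 (4.94-fold), Ap3b2 (4.08-fold), Nfasc (3.80-fold), Dmrt3 (3.53-fold), Esrrb and Prap1 (at least 2.32-fold). Dmrt3, another DM domain gene, rose 3.79-fold in 129Sv. The largest falls besides Dnmt3l were those of Rrad (19.1-fold), Afp (14.7-fold), Islr2 (14.2-fold), Dpep3 (at least 12.2-fold), Gm364 (at least 11.9-fold), Tmem232 (at least 11.6-fold), Nlrp4f (at least 11.5-fold), Ldhc, which encodes a germ cell lactate dehydrogenase (at least 9.11-fold), and 4933402E13Rik (at least 4.71-fold). Of the 19 Sertoli cell genes, Cst9 (2.54-fold), Sox8 (2.24-fold) and Hsd17b3 (1.58-fold) fell and none rose, without a shift of the list (camera adjusted p = 0.215, but 0.0371 with the Actb ratio as a covariate). Of the ovarian somatic cell genes Wnt4 rose 1.75-fold, and of the neuron and muscle genes Tubb3 (2.11-fold) and Th rose and Myh3 fell. No gene of the endothelial, macrophage and leukocyte, interstitial and peritubular, fetal Leydig, red blood cell, adrenal cortex or cell division lists passed in B6. limma called 1005 genes, 312 higher and 693 lower in the knockout. Without the 2 arrays of the highest Actb 3′ to 5′ ratio, B6 knockout replicate 3 and 129Sv knockout replicate 1, 835 genes passed. Of these, 712 were shared with the 1005 in the same direction. The count of male germ cell genes that fell was 13, while the shifts of the general germ cell and meiosis lists no longer passed (camera adjusted p = 0.0814 and 0.216). With the Actb ratio as a covariate 618 genes passed. Leaving out a single array gave 430 genes without B6 wild-type replicate 3, 631 without B6 wild-type replicate 2 and up to 1273 without B6 knockout replicate 1.

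The knockout effects of the strains overlapped. Of the genes that rose, 120 were called in both strains, where 12.7 would be shared by independent lists of these sizes, and of the genes that fell, 264 were shared against 29.4. A further 8 genes were called in both strains in opposite directions. The log2 differences of all tested genes correlated with Pearson's r = 0.518 and Spearman's rho = 0.265 across genes, which are not independent replicates, and the 2 effects share no array. Averaged over strains, 1718 genes passed, 715 higher and 1003 lower. With the title number as a covariate 974 passed, 315 of them higher. L1td1 (log2 difference 4.24 ± 0.30, adjusted p = 4.17e-07) and Lhx1 (2.91 ± 0.38) rose and Rrad (-3.45 ± 0.35, adjusted p = 1.18e-05) fell with all group means above the filter. For the other genes named by the rule some group means lay below a log2 value of 4, and with values below 4 set to 4 Otx2 rose and the averages were 3.55 for Svopl, 2.20 for Trh and 1.97 for Prap1, and -3.30 for Dpep3, -3.24 for Dscaml1, -2.62 for 4933402E13Rik, -2.37 for Dntt and -1.87 for Svs4, each past the threshold. Of the lists, pluripotency and early germline had 13 genes that rose and 3 that fell (camera adjusted p = 5.9e-09, adjusted p = 0.696 with an estimated correlation), male germ cell and piRNA pathway had 14 that fell and none that rose (camera adjusted p = 6.76e-13, adjusted p = 0.426 with an estimated correlation), Sertoli cell had 4 that fell (camera adjusted p = 0.0413, adjusted p = 0.696 with an estimated correlation), and neuron and skeletal muscle had 3 that rose and 1 that fell (camera adjusted p = 0.0413 upward, adjusted p = 0.696 with an estimated correlation). The Sertoli cell and the neuron and muscle shifts of the average did not pass with the title number as a covariate (0.052 each) or without some single arrays (adjusted p up to 0.167 and 0.504).

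**Figure D2:**
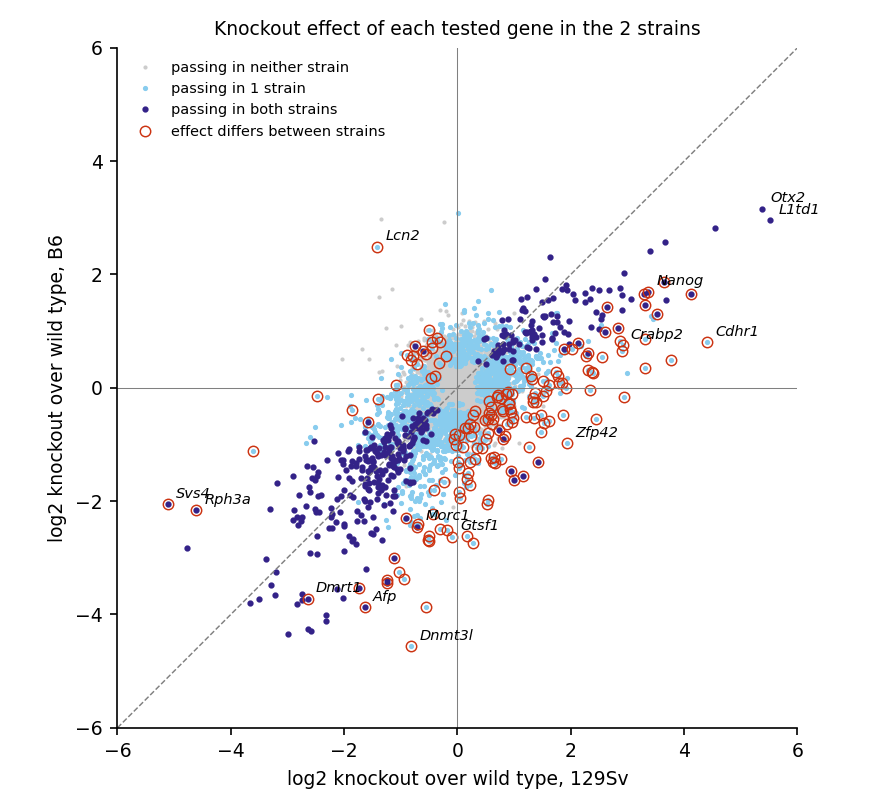
Log2 difference of knockout over wild type for each of the 12726 tested genes, 129Sv on the horizontal axis and B6 on the vertical axis, with the dashed line at equal effects, colours for genes that passed in neither strain, 1 strain or both, and red rings for the 167 genes whose effect differed between strains. L1td1 and Otx2 rose in both strains, Dnmt3l lies low on the B6 axis, and r across genes is 0.518.

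The test of the difference between the 2 knockout effects separated germ cell genes by strain. The mean log2 level of the general germ cell list was 7.767 to 8.353 in B6 knockouts and 8.742 to 8.925 in B6 wild types. In 129Sv it was 9.406 to 9.579 in knockouts and 9.214 to 9.335 in wild types. A lower share of germ cells in B6 knockouts could therefore be part of these differences, and was not separated from them. Dnmt3l fell in B6 but differed by -0.82 ± 0.52 on the log2 scale in 129Sv (adjusted p = 0.411), and the effects differed by 3.73 ± 0.73 (adjusted p = 0.0266). Gtsf1, a piRNA pathway gene, fell by 2.62 in B6 and differed by -0.09 ± 0.22 in 129Sv (difference 2.54 ± 0.31, adjusted p = 0.0012). Zfp42, a marker of pluripotent cells, rose by 1.94 in 129Sv and differed by -0.98 ± 0.29 in B6 (difference 2.91 ± 0.41, adjusted p = 0.00314). Nanog rose in both strains, more so in 129Sv (difference 1.67 ± 0.31, adjusted p = 0.0208). In the pluripotency list Zfp42, Lin28a (2.14 ± 0.40), Sox2 (1.79 ± 0.35), Fbxo15 (1.69 ± 0.24) and Nanog passed the test of the difference, all toward higher values in 129Sv, and 16 did so when adjusted over the list alone (camera adjusted p = 3.81e-10, adjusted p = 0.249 with an estimated correlation). Without B6 knockout replicate 3, in which the list lay at the wild-type level, the camera adjusted p was 1.64e-08. In the male germ cell and piRNA list Dnmt3l, Morc1 (1.74 ± 0.27), Tdrd5 (1.44 ± 0.24) and Asz1 (1.10 ± 0.17) passed, and adjusted over the list alone 9 were more positive and 1 more negative in 129Sv (camera adjusted p = 3.16e-07, adjusted p = 0.249 with an estimated correlation). Gtsf1 and Taf7l (1.53 ± 0.25) passed among the general germ cell genes, where the list's p was 1.41e-06 (adjusted p = 0.111 with an estimated correlation), and Sycp3 (1.57 ± 0.29) passed among the meiosis genes, where it was 5.23e-06 (adjusted p = 0.111 with an estimated correlation).

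**Figure D3:**
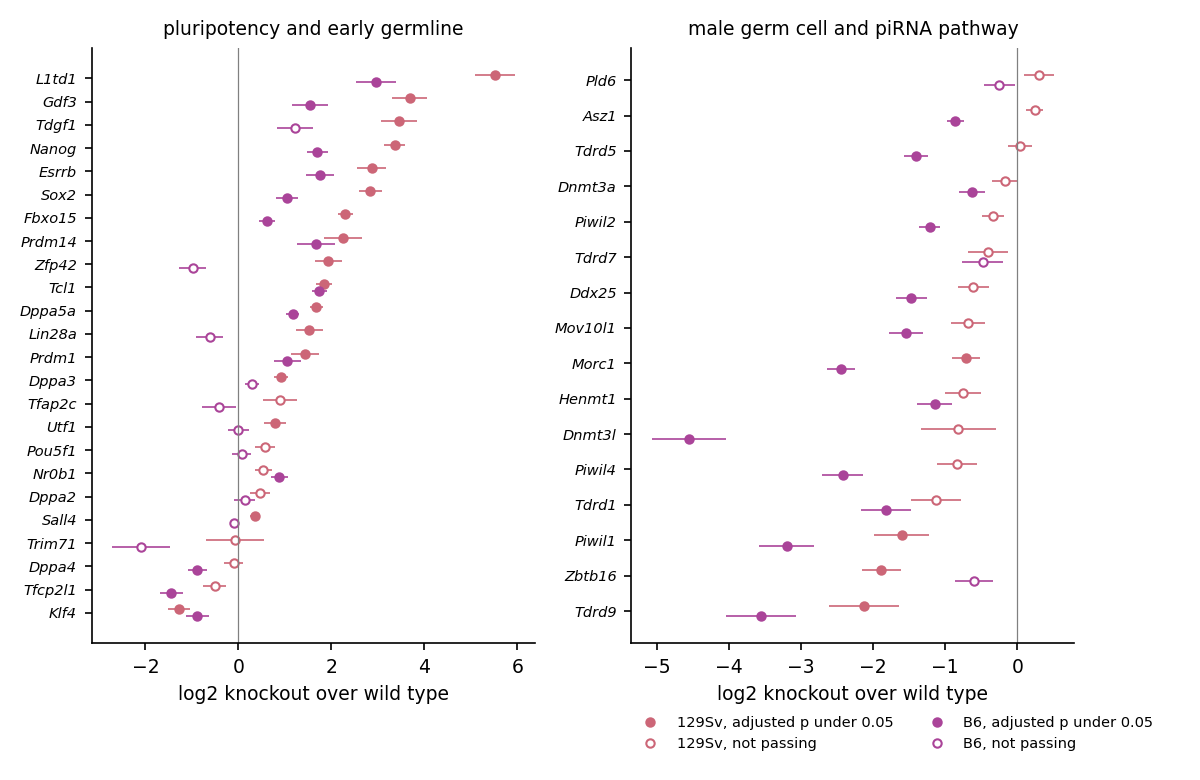
Log2 difference of knockout over wild type with its SE for the 24 tested genes of the pluripotency and early germline list and the 16 of the male germ cell and piRNA pathway list, in 129Sv and B6, with filled points at an adjusted p under 0.05. In the pluripotency list 16 genes rose in 129Sv and 11 in B6, and in the male germ cell list 4 fell in 129Sv and 13 in B6.

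Other genes with the largest differences of this kind were Cdhr1 (3.61 ± 0.38), Gm364 (3.31 ± 0.31), Eras (3.28 ± 0.68), the SOX family gene Sox3 (3.10 ± 0.46) and AU018091 (3.02 ± 0.33). In the opposite direction were Lcn2 (-3.91 ± 0.89), Svs4 (-3.05 ± 0.62), Asb17 (-2.50 ± 0.53), Rph3a (-2.45 ± 0.32), Klrb1a (-2.32 ± 0.39) and Zfyve27 (-1.51 ± 0.27). Svs4, Asb17 and Klrb1a had mean log2 values between 3.45 and 3.98 in B6 wild type, close to background, so a fall in B6 could not have been measured in full. Cdhr1, Gm364, Sox3, AU018091 and Rph3a also had group means below 4. With values below 4 set to 4 the differences of these 8 genes were -2.85, -2.27, -2.23, 3.75, 2.96, 3.00, 2.81 and -2.42, each past the threshold. Of the single members of other lists, Crabp2 (2.15 ± 0.34), Afp (2.24 ± 0.44) and Lef1 (1.21 ± 0.17) passed toward higher values in 129Sv. The endothelial and fetal Leydig cell lists were shifted the other way (camera adjusted p = 0.000208 and 0.00561, adjusted p = 0.174 and 0.288 with an estimated correlation), although none of their genes passed alone. In all, limma called 167 genes, 142 more positive and 25 more negative in 129Sv. Of these, 62 rose in 129Sv without passing in B6, 50 fell in B6 without passing in 129Sv, 23 passed in both with the same sign and 8 with opposite signs. A further 11 fell in 129Sv without passing in B6, 8 rose in B6 without passing in 129Sv and 5 passed in neither strain. Leaving out 129Sv wild-type replicates 1, 2 or 3 gave 39, 73 or 49 genes, 129Sv knockout replicates 1, 2 or 3 gave 100, 64 or 65, B6 wild-type replicates 2 or 3 gave 48 or 73, and B6 knockout replicates 1 or 2 gave 300 or 111. With the title number as a covariate 20 genes passed, all of them among the 167.

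Between the wild-type testes of the strains, male germ cell genes were higher in 129Sv. The last title number separates the strains fully, so any effect of it would be part of the strain differences. The mean log2 level of the general germ cell list was higher as well, 9.214 to 9.335 in 129Sv and 8.742 to 8.925 in B6 wild types. Of the 16 male germ cell and piRNA pathway genes, 7 were higher in 129Sv and none lower, and 10 were higher when adjusted over the list alone (median 0.64 on the log2 scale, camera adjusted p = 0.00176, adjusted p = 0.781 with an estimated correlation). Of the 20 meiosis genes 8 were higher, among them Syce3 (3.07-fold), Sycp2 (2.72-fold) and Stag3 (2.33-fold), and Dmc1 (2.57-fold) and Stra8 (2.40-fold) were lower. Macrophage and leukocyte genes were shifted downward in 129Sv with no single gene of 16 passing (camera adjusted p = 0.00234, adjusted p = 0.781 with an estimated correlation). This shift rests on B6 wild-type replicates 1 and 2, with mean log2 levels of the list of 7.325 and 7.332. B6 wild-type replicate 3, at 6.444, lay below all 129Sv wild types (6.473 to 6.699). Of the pluripotency list 2 genes were higher and 2 lower, and of the 19 Sertoli cell genes 2 were higher and 2 lower, among them Mro, 16.3-fold lower in 129Sv (-4.03 ± 0.25, adjusted p = 1.43e-07). The cell cycle inhibitor gene Cdkn2b was 2.94-fold and Rb1 2.27-fold higher in 129Sv.

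Besides Mro, the genes with the largest strain differences in wild type lay outside the lists. Tmem87a was at least 96.3-fold higher in 129Sv (log2 difference 7.18 ± 0.22, SE, n = 3 per group, adjusted p = 3.44e-11), followed by Cyp2c55 (19.3-fold), Htr1b (at least 17.6-fold), Rbm45 (16.1-fold), Ngp (14.9-fold), Polr3gl (12.3-fold), Svs4 (at least 9.83-fold), Igsf23 (9.73-fold), Gchfr (9.62-fold) and Phyhip (at least 6.45-fold). Abcb10 was 22.6-fold lower in 129Sv (-4.50 ± 0.27, adjusted p = 8.35e-08), B3galt6 20.4-fold lower and Khdc1a 14.0-fold lower, and Zfp874a (at least 14.5-fold), Trim12a (at least 9.59-fold), Galc (at least 7.21-fold), Ang (at least 6.15-fold), 2610507I01Rik (at least 5.59-fold) and Zfp429 (at least 4.85-fold) were lower as well. Weaker probe sets of some of these genes gave smaller log2 differences, -1.787 for B3galt6, -1.202 for Abcb10 and -0.543 for Galc, with means of 5.05, 4.08 and 4.61 in the higher group. The log2 levels of Zfp874a and Zfp429 varied between the 129Sv knockout arrays with SDs of 2.56 and 1.48. That of Ngp varied in B6, with an SD of 1.93 in wild types and 2.22 in knockouts. In knockouts the mean of Ngp was 6.92 in 129Sv and 7.35 in B6, so its strain difference was not seen there. limma called 2054 genes, 1393 higher and 661 lower in 129Sv. Of 184 called genes with at least a 2-fold difference and a further probe set above the filter, that probe set went the same way in 82.6% (exact 95% interval 76.3% to 87.8%), against 94.4% of 216 knockout calls. Leaving out a single array gave 1030 genes without 129Sv wild-type replicate 2, 1246 without 129Sv wild-type replicate 3, 1119 without B6 wild-type replicate 1, 1279 without B6 wild-type replicate 2 and up to 2849 without B6 knockout replicate 3.

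Between the knockout testes of the strains the germ cell lists stood farther apart. A different share of germ cells in the 2 knockout groups could be part of this, and was not tested. Of the 16 male germ cell and piRNA pathway genes, 15 were higher in 129Sv knockouts than in B6 knockouts (median 1.62 on the log2 scale, camera adjusted p = 1.39e-08, adjusted p = 0.252 with an estimated correlation), and Dnmt3l was 31.9-fold higher (5.00 ± 0.52, adjusted p = 8.02e-06). Of 13 general germ cell genes 12 were higher and 1 lower (camera adjusted p = 1.38e-05, adjusted p = 0.157 with an estimated correlation), of 20 meiosis genes 14 were higher (camera adjusted p = 4.69e-06, adjusted p = 0.103 with an estimated correlation), and of 24 pluripotency genes 18 were higher and 1 lower (camera adjusted p = 4.49e-06, adjusted p = 0.543 with an estimated correlation). Several lists of somatic cells and leukocytes were lower in 129Sv knockouts, with 8 of 11 endothelial genes (camera adjusted p = 0.000137, adjusted p = 0.157 with an estimated correlation), 9 of 16 macrophage and leukocyte genes (camera adjusted p = 0.000356, adjusted p = 0.578 with an estimated correlation), 6 of 8 fetal Leydig cell genes (camera adjusted p = 0.00163, adjusted p = 0.498 with an estimated correlation) and 8 of 19 Sertoli cell genes (camera adjusted p = 0.0374, adjusted p = 0.61 with an estimated correlation). The Sertoli cell shift did not pass without 129Sv knockout replicate 2 (0.105), with the mean of probe sets (0.0751) or with replicate numbers as a block within strain (0.147). Single arrays moved these counts, the endothelial one to 2 without 129Sv knockout replicate 2 and to 5 without B6 knockout replicate 3, and the macrophage one to 4 without 129Sv knockout replicate 1 or 3 and to 5 without B6 knockout replicate 3. Without the 2 arrays of the highest Actb ratio they were 6 and 2. Of 9 ovarian somatic cell genes 3 were higher and 1 lower in 129Sv knockouts, with no shift of the list (camera adjusted p = 0.967). Examples of the lower genes were Robo4 (2.09-fold), Lyz2 (2.77-fold), Cyp17a1 (1.78-fold) and Amh (2.01-fold). The genes farthest apart were Tmem87a (at least 105-fold), Dnmt3l, Nlrp14 (at least 9.82-fold), Cyp2c55 (at least 7.48-fold), Gbp2b (at least 3.92-fold) and Magea5 (17.1-fold), higher in 129Sv, and B3galt6 (log2 difference -4.58 ± 0.16), Mro (18.1-fold), Abcb10 (15.0-fold), Dubr (13.4-fold), Trim12a (at least 9.07-fold) and Galc (at least 6.33-fold), lower in 129Sv. limma called 4345 genes, 2585 higher and 1760 lower in 129Sv.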

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

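The knockout effects of the strains differed in 167 genes by the test of the difference, and most of these lay higher in 129Sv. In members of the fixed germ cell, meiosis and pluripotency lists the differences in log2 units were Dnmt3l 3.73, Zfp42 2.91, Gtsf1 2.54, Lin28a 2.14, Sox2 1.79, Morc1 1.74, Fbxo15 1.69, Nanog 1.67, Sycp3 1.57, Taf7l 1.53, Tdrd5 1.44 and Asz1 1.10. Other genes were Cdhr1 3.61, Gm364 3.31, Eras 3.28, Sox3 3.10, AU018091 3.02, Dnmt3b 1.91, Trh 2.46, Afp 2.24, Apela 2.23, Crabp2 2.15, Mep1b 1.78, Lef1 1.21 and Dmrt1 1.08, of which Cdhr1, Gm364, Sox3, AU018091, Trh, Apela and Mep1b had group means below a log2 value of 4, so that their sizes are not exact. The opposite sign was found for Zfyve27 at -1.51, Klrb1a at -2.32, Rph3a at -2.45, Asb17 at -2.50, Svs4 at -3.05 and Lcn2 at -3.91. Of these, Klrb1a, Rph3a, Asb17 and Svs4 had group means below 4 too, and with values below 4 set to 4 they lay at -2.23, -2.42, -2.27 and -2.85. Of 2311 tested probe sets without a gene name, 43 changed in 129Sv knockouts, 19 of them upward, and 45 changed in B6 knockouts, 13 of them upward.

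The tests of the fall of male germ cell genes in B6 knockouts below, on general germ cell genes and on arrays of low RNA integrity, were chosen only after the result was seen. The male germ cell and piRNA pathway list had a median log2 difference of -1.44 in B6. If a lower share of germ cells were the whole cause, general germ cell genes might be expected to fall by about as much, but 8 of 13, Dazl and Ddx4 among them, lay above that median by more than 2 standard errors and 2, Brdt and Gtsf1, lay below it. The medians of other cell types went the way a lower share of germ cells would give in the red blood cell (0.476), endothelial (0.366), fetal Leydig (0.263), macrophage and leukocyte (0.238) and interstitial (0.203) lists but not in the Sertoli cell list (-0.088), and none of these lists passed camera in the main analysis, although the fetal Leydig list did with the mean of probe sets (0.0312). Lower RNA integrity is an unlikely cause, because 13 male germ cell genes were called lower after B6 knockout replicate 3 and 129Sv knockout replicate 1 were left out. A smaller part played by the share of germ cells, or a delay of male germ cell development, could remain, since marker genes of bulk testes do not count cells.

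Relabelled arrays limit what the counts of genes could mean, and the expected outcomes of these splits were written down before they were run, with the counts themselves already known. For the knockout in 129Sv, the knockout in B6, the strains in wild type and the strains in knockout, 1 of 10 splits, the real one, gave as many genes and the highest other gave 0, and 10 splits are too few for a share under 0.05. For the average effect 1 of 100 splits gave as many genes as the real 1718, and the highest other gave 377. For the difference of the effects between strains 8 of 100 splits gave at least the real 167, but this test is void, because relabelling across genotypes carries the knockout effect into the difference. The highest other, 1718, comes from exchanging the genotypes in 1 strain, which turns the difference into the average, and splits that exchange only part of the arrays carry a part of that effect. Whether arbitrary grouping could give the 167 genes is therefore left open by these splits.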

How the results depend on the processing

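Filters, probe rules, normalisations, models and left-out arrays were chosen before the data were examined, except the Actb ratio tests, and the cause of the shifts below was not tested. With 3 arrays per group the counts depended on the choices. A 2-fold threshold left 549 genes for the knockout in 129Sv, 495 in B6, 739 between wild types, 1334 between knockouts and 485 for the average. A filter at a log2 value of 6 gave 696 genes in 129Sv and a pluripotency p of 0.11 in B6. The mean of probe sets gave 108 genes for the difference of effects and turned Rnf17 in B6 to -0.55 (adjusted p = 0.116). Testing every probe set gave 74 for the difference, 3369 between wild types, 7439 between knockouts and r = 0.452. A floor at 4 gave r = 0.44 and turned the difference for Ret to -1.40 (adjusted p = 0.00138). Array weights gave 2092, 2166, 779, 3461 and 3106 genes for 129Sv, B6, the difference, the wild types and the average. The title number as a covariate gave 347 genes in 129Sv, 20 for the difference, 1225 between wild types and 974 for the average. The Actb ratio as a covariate gave 618 genes in B6 and r = 0.582, and a fit of only the groups compared gave 490 in B6. Among gene-level rows 11532 stayed the same, 240 were stronger, 479 weaker and 2 reversed.

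Replicate numbers as a replicate block within strain gave 653 genes in B6 and 77 for the difference, and residuals of the same number correlated near 0 or negatively. In B6 the titles of replicates 1 and of replicates 2 share a number between wild type and knockout, whose meaning is not given in the sources used here. As a random block this number gave a correlation of 0.158, 1166 genes in B6 and 201 for the difference.

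With an estimated correlation the list p-values rose to 0.477 for pluripotency and for male germ cell genes in 129Sv, 0.643 and 0.254 in B6, and 0.249 for both in the difference. fry gave 0.0555 for male germ cell genes in 129Sv and 0.125 for pluripotency in B6. It also passed lists that camera did not. In 129Sv these were the germ layer (0.00157), Nodal and activin (0.00342), ovarian somatic (0.00138), meiosis (0.0283), G1 to S (0.0404), apoptosis and p53 (0.0356) and stress (0.048) lists. In B6 they were the Nodal and activin (0.0278) and DM domain (0.00435) lists, the latter including Dmrt1 itself. In the difference they were the germ layer and ovarian somatic lists (0.0419 each). There fry did not pass the fetal Leydig (0.0547), DM domain (0.0528) and Y-linked (0.0547) lists, which camera had passed. By camera the germ layer list passed in 129Sv without a filter (0.00981), and the meiosis list without 129Sv knockout replicate 1 (0.0145). The meiosis list also passed there without the 2 arrays of the highest Actb ratio (0.00644). Among other calls gained by camera, the germ layer list passed in the difference without a filter (0.00649) and with either replicate block (0.033 and 0.0318). In B6 the DM domain list passed with the mean of probe sets (0.000387) and with the Actb ratio as a covariate (0.0371).

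Leaving out single arrays gave 596 to 1561 genes in 129Sv, 430 to 1273 in B6, 39 to 300 for the difference, 1030 to 2849 between wild types, 3136 to 4316 between knockouts, 1209 to 1883 for the average, r from 0.434 to 0.583, and p from 1.51e-06 to 0.284 for pluripotency in B6.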

Other observations

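Cell cycle and death regulators changed in few members. Of 15 G1 to S regulators Cdkn1a, the gene of the inhibitor p21, rose 2.60-fold and Ccnd1 1.61-fold in 129Sv knockouts while Ccnd2 fell 1.36-fold, and in B6 knockouts Ccnd1 rose 1.46-fold while Cdkn2a fell 1.92-fold and Ccnd2 1.36-fold. Of 13 apoptosis and p53 genes Pmaip1 rose 3.28-fold in 129Sv and 1.95-fold in B6, and Bcl2l11 fell 1.48-fold in 129Sv. Of 10 stress and RNA quality genes Egr1 fell 2.60-fold and Hspa1a 1.59-fold in 129Sv, and none passed in B6. Of 5 mesonephric duct and tubule genes Pax8 fell 3.69-fold in 129Sv and none passed in B6. Of 9 ubiquitous genes none passed in 129Sv, and Tbp fell 1.66-fold in B6. None of these lists was shifted as a whole in a knockout comparison (smallest camera adjusted p = 0.278), whereas fry, which tests a list by itself, passed in 129Sv for the G1 to S (0.0404), apoptosis and p53 (0.0356) and stress (0.048) lists.

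Of the DM domain family, 5 were tested, and besides Dmrt1 and Dmrt3 Dmrtc2 fell at least 1.17-fold in B6. Of 3 Y-linked genes Kdm5d rose 1.51-fold in 129Sv. In the difference of effects the DM domain list and the Y-linked list were shifted toward 129Sv (camera adjusted p = 0.0161 and 0.0362, adjusted p = 0.249 for each with an estimated correlation). The DM domain list includes Dmrt1, the removed gene itself, so its shift in part restates the knockout. Both calls are fragile. The DM domain call ended without 129Sv knockout replicate 1 (0.0506) or B6 knockout replicate 2 (0.0567), with a filter at a log2 value of 6 (0.0752) and with the title number as a covariate (0.0691). The Y-linked call ended without any of 6 single arrays (adjusted p from 0.0503 to 0.0942), with the mean of probe sets (0.131) and with the title number as a covariate (0.0818).

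The expected outcomes of the tests of second probe sets were written down before they were run, with the strain calls themselves already known. Sequence differences under probes could produce strain calls, and they may account for part of them. As the whole cause they had been expected to leave second probe sets without direction. That expectation need not hold, because probe sets of a gene may overlap or lose signal in the same strain. The test therefore cannot decide whether sequence differences are the whole cause. Second probe sets went the same way in 82.6% of 184 genes. The share among 216 knockout calls, pooled over the strains, was 94.4%, and the difference (Fisher p = 0.000185) may reflect such an effect in part of the genes. A gene called in both strains entered this pool once for each strain, and the Fisher test treats such repeats as independent.

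For B6-like levels of strain marker genes in 129Sv knockouts all tests, the limits that defined the marker genes included, were chosen only after the result was seen. Of 105 genes that separate the wild types, 9 were B6-like in 129Sv knockout replicates 2 and 3 but not in 1. They were Fam171a1, E330017L17Rik, Arg2, Spock1, Prxl2c, Rsl1, Zfp429, Zfp874a and Arsk. Among them were 5 neighbouring pairs, against a mean of 0.57 in 10000 random shuffles of their places (one-sided permutation p = 2e-04). All 5 pairs lie in a single run from Spock1 to Arsk on chromosome 13, which may be a segment of the B6 strain. Fam171a1, E330017L17Rik and Arg2, on chromosomes 2, 4 and 12, had no neighbour of this pattern on their chromosome. The test therefore says nothing of segments there. Lower RNA integrity is unlikely, since 0 of these 2 arrays had an Actb ratio above all 129Sv wild types (2.75 and 2.73 against up to 3.91). This test replaced earlier counts that decide nothing, namely of genes on the B6 side in replicates 1, 2 and 3 (12, 26 and 17 of the 105) and of genes B6-like in replicate 1 alone. Of 18 values 17 lay nearest the average of the wild-type levels, which may reflect 1 copy of each strain at these genes. The genes were, however, selected for lying nearer the B6 than the 129Sv level, so the 129Sv level could not be the nearest. That selection left both the average and the B6 level possible, and neighbouring zinc finger genes can share regulation.

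Rsl1, Zfp429 and Zfp874a, all in the run on chromosome 13, passed in the 129Sv knockout comparison. A part of that comparison might therefore follow a strain segment instead of Dmrt1. The title number as a covariate, which leaves 347 genes, could be tested against genotypes of the embryos, which are not given in the sources used here.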
